A study of Arabidopsis thaliana with 2 samples.

How the data were processed

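RNA of immature flower bud clusters of Arabidopsis thaliana, accession Col-0, was measured in 2 libraries, 1 single-stranded RNA library and 1 library of ribosome-bound RNA, with no replicates, per the labels. Per the labels' protocols, ribosomes were pelleted through sucrose and spread over a 15 to 60% sucrose gradient, monosome and polysome fractions were pooled, and their RNA was depleted of ribosomal RNA and fragmented before library preparation. Fragmented RNA was sequenced, so the library measures RNA bound to ribosomes and not ribosome footprints. The label of the single-stranded library names treatment with a double-strand-specific nuclease and gives RNase ONE as that enzyme. RNase ONE is known to cut single-stranded RNA, so the label is at odds with itself, and the library is described here by its name.

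Per the submitters' processing notes, cutadapt 0.9.5, Bowtie 0.12.7 and genome build TAIR9 were used for both libraries. The hotspot caller and the program that produced the table are not given in the sources used here. The deposited hotspots are genome intervals with a strand and a score for each, and the deposited name of the list carries an FDR of 5%. Per the file's names, hotspots were numbered up to 276389, of which 33187 are listed (12.0%). The deposited score is always below 0 and its formula is not given in the sources used here. From the values, 92.7% of the scores equal the negative base 2 logarithm of n plus the square root of n squared plus 1, for whole n from 1 to 6 (tolerance 0.01). That n is called read equivalents here, as a description of the scale only. A further 25 hotspots had much stronger scores, and no score lay between -3.59 and -10.03.

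The deposited table gives for each transcript the count of clones, per the file headers, and an estimated count in which clones were weighted by the authors, which never exceeds the first. The weights and their reason are not given in the sources used here. Per the file headers the RPM values were made by the authors, and they equal the weighted clones scaled to the 9574408 mapped clones. The deposited RPKM equals the RPM per kb of the listed transcript length. The ratio of weighted to unweighted clones is the mean weight per clone, and 8527 genes above 0 had a value under 0.5. It follows sequence present at other places of the genome in part. The median was 0.269 for the 609 genes with at least 0.5 of their exon 20-mers at other places and 0.680 for the 1008 genes with none, of which 24.0% (21.4 to 26.8) were still under 0.5. The mean weight is therefore not used as a measure of clones that map to several places on its own. Over all genes, with the best isoform each, the weighted clones came to 3.72% of the mapped clones, so most mapped clones lie outside the listed transcripts or in clones weighted down. The median gene above 0 rested on 3.5 weighted clones (quartiles 1.14 and 9.33), and 23.3% of genes had at least 10, which makes single values of low genes imprecise. Counting intervals on RPKM are 95% Poisson intervals on the weighted clones. The depth of the single-stranded library is not given in the sources used here, so hotspots carry no interval of their own.

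Genes and gene names came from the RefSeq annotation of TAIR10.1, and 30548 of the 31280 gene identifiers were found in it. The hotspot positions are in TAIR9. Both were set together on the nuclear chromosomes only after a check of register: 82.9% of hotspot bases lay in exons of a representative mRNA on the same strand, against 64.7% after a move of 100 nt, 45.7% after 1000 nt and 23.5% after 10000 nt. Over whole chromosomes and their last parts the lowest share was 80.2%, and the highest after a move of 1000 nt was 48.1%. Organelle hotspots were not assigned to genes. The annotation used holds no transposable element features, so that class was not analysed here and a pseudogene class was used in its place.

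For each nuclear protein-coding gene, the isoform with the longest coding sequence among those in both sources was used, which gave 26632 genes, 23423 of them with an RPKM above 0. The isoform had the same length in both sources for 22.2% of them. A gene had a hotspot where at least 1 base overlapped its exons on the same strand. A hotspot on several transcripts was assigned, for placement, to the one with most of its bases. Each hotspot was placed 1000 times at random inside its own spliced transcript, and an observed value outside the 2.5 to 97.5 percentile range was read as a departure. Windows of 100 nt and bins of 20 nt around the codons used mRNAs with both UTRs of at least 100 nt and a coding sequence of at least 200 nt.

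Before the data were examined, 13 gene lists with 321 entries were fixed, along with the rule for named genes: the 20 nuclear protein-coding genes of highest RPKM, the 3 highest and the 1 lowest member of each list, the 10 genes with the most hotspot bases, the 5 hotspots of strongest score, the 5 genes of highest RPKM without a hotspot and the 5 genes with the most hotspot bases at or below the median RPKM. A gene that this rule takes is not reported here. A list median was set against 10000 random lists of the same size, and a hotspot share against 10000 lists matched on RPKM decile. These percentiles describe the libraries and are not p-values. Spearman's rho had 1000 bootstrap draws over genes. No fold change on a log scale was computed, and pseudocounts of 1 and 0.1 entered only the alternative Pearson correlations.

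Alternatives fixed in advance were an RPKM minimum of 1, genes at 0 included, matching on transcript length, strata of transcript length, hotspots better than the median score, hotspot midpoints, strand ignored, the isoform numbered 1 and a UTR minimum of 50 nt, as well as an overlap of most of the hotspot and Pearson correlations. Chosen after seeing the data were a mean weight of at least 0.5 per clone, hotspots of at least 3 read equivalents, transcripts of equal length in both sources, single-exon transcripts, the shortest and the longest transcripts for the shares by RPKM decile, and for the same shares genes with a share under 0.1 of exon 20-mers at other places of the genome, on either strand, organelles included. The windows beside the codons on the equal-length and single-exon transcripts were also set against 1000 random sets of as many mRNAs, a comparison chosen after seeing the data.

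Predicted folding was computed with RNAfold 2.7.2 at its default settings for 5000 of the 18750 hotspots that lay wholly in 1 coding sequence at least 2 times their length, leaving out the strongest scores, and for a random segment of equal length from the same coding sequence. The segment was drawn from anywhere in that sequence and could overlap the hotspot. Each sequence was also folded as 10 shuffled copies with the same bases and 10 with the same pairs of neighbouring bases. Shared sequence was searched as exact 20-nt matches on either strand between transcripts and annotated tRNA, snRNA, snoRNA and rRNA, with 5000 nt on each side of the 4 nuclear rRNA genes, and the organelle genomes. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.

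The statistics were tested on simulated data. With the 27828 real hotspots placed uniformly, 3 of 40 simulations put the coding share outside its limits, and the same number held for each UTR. After hotspots centred in 5′ UTRs were thinned by a factor of 2, the 5′ UTR ratio came out at 0.574 with percentile 0, above 0.5 because hotspots across the boundary were kept. Among 23423 genes, 13 of 200 random lists of genes fell outside the limits, and 197 of 200 lists with RPKM multiplied by 4 were found. Of 200 random lists, 10 had hotspot shares outside the limits, and 191 of 200 lists with their hotspots cut by a factor of 2 were found. A known correlation lay in its interval in 37 of 40 simulations, and a known paired difference in 190 of 200. Of 100 random sets of mRNAs, 4 lay outside the limits, and all 100 sets with upstream bases cut by a factor of 2 were found.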

Results

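Unopened, immature flower bud clusters of the Arabidopsis accession Col-0 were profiled with 2 libraries, 1 per assay. The first was a single-stranded RNA library, deposited as 33187 hotspots, which are stretches of 50 to 1533 nt on a given strand. How the authors called them, and against what background, is not given in the sources used here. The second was a library of RNA recovered from pooled monosomes and polysomes, deposited as a table of 37318 transcripts of 31280 genes. It held 9574408 mapped clones. The series title names RNA secondary structure across the transcriptome as the subject, and the files allow the location of hotspots to be set beside the ribosome-bound abundance of the same genes. Because each assay had a single library, no difference has a replicate check, no p-value across genes is given, and every interval covers counting error, resampling of genes or random placement only.

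Among the 13 fixed gene lists, those of photosynthesis, cytosolic ribosomal proteins, translation factors, core histones and the tapetum had the highest median ribosome-bound RNA. The median gene here is the median of the nuclear protein-coding genes with an RPKM above 0, at 0.245 RPKM. All 34 nuclear photosynthesis genes lay above the median gene, with a list median of 28.9 RPKM, 118-fold over it. PSBR, a subunit of photosystem II, stood at 84.3 RPKM (95% counting interval 77.5 to 91.4), CAB1 at 64.6 RPKM and LHCB5 at 55.2 RPKM, both light-harvesting proteins. The lowest member, PSAG of photosystem I, still stood at 3.76 RPKM. The 49 cytosolic ribosomal protein genes had a median of 6.51 RPKM, from 22.4 RPKM for RP1 through 18.3 RPKM for EMB2296 and 15.7 RPKM for SAC52 to 0.885 RPKM for AT3G13580. All 49 lay above the median gene.

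Translation factors had a median of 6.36 RPKM, and 18 of 19 lay above the median gene. The elongation factor genes AT5G60390, LOS1 and AT1G07920 stood at 29.5, 21.6 and 16.7 RPKM, and ELF5A-1 was lowest at 0.147 RPKM, with an upper counting limit of 0.803. AT1G07920 had a mean weight of 0.304 per clone. Among the 13 members with a mean weight of at least 0.5, a setting chosen after seeing the data, the list median was 2.44 RPKM (percentile 99.99), below the 2.80 RPKM of the tapetum list under the same setting. Core histones had a median of 5.41 RPKM, with all 30 genes above the median gene. AT4G40040 led them at 18.7 RPKM, followed by HTB4 at 14.0 RPKM and AT5G59690 at 13.0 RPKM, and HTA8 was lowest at 0.484 RPKM. Each of these 4 lists had a higher median than every one of 10000 random lists of the same size (percentile 100). Histone and light-harvesting genes belong to families with near-identical copies, and CAB1 had a mean weight of 0.452 per clone, so its level rests on the authors' weights.

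Genes of the tapetum and the pollen wall were the highest of the flower lists. The tapetum is the anther layer that feeds developing pollen. Of 26 genes, 22 lay above the median gene, and the list median of 2.75 RPKM was 11.2-fold over it (percentile 100). ATA27 stood at 19.999 RPKM (17.99 to 22.18), the glycine-rich pollen coat protein gene GRP17 at 16.1 RPKM (14.3 to 18.1) and the extracellular lipase gene EXL4 at 15.1 RPKM (13.02 to 17.43). DYT1, a transcription factor of early tapetum development, was lowest at 0.0837 RPKM, from less than 1 weighted clone, with an upper counting limit of 0.782. ATA20, an anther gene outside the list, ranked among the 20 highest genes at 52.6 RPKM. Mature pollen and sperm genes stood lower, with a median of 0.423 RPKM (percentile 90.7). Their highest members were sks11 at 2.53 RPKM, VGD1 at 1.84 RPKM and the pectin methylesterase gene PPME1 at 1.39 RPKM, and HAP2, a sperm fusion protein, was lowest at 0.0465 RPKM.

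Floral organ and meristem regulators had a median of 0.482 RPKM (95% bootstrap interval over genes 0.271 to 0.852), and 20 of the 27 genes above 0 exceeded the median gene. The list median lay at percentile 98.4. The petal and stamen identity gene PI was highest at 7.71 RPKM (6.12 to 9.59), followed by SEP3 at 2.57 RPKM (1.71 to 3.71) and AP3 at 1.99 RPKM (1.21 to 3.08). CLV3, which encodes a stem cell signal peptide, was listed at 0, which allows up to 0.747 RPKM. This call depended on the genes kept: among genes with a mean weight of at least 0.5 per clone the percentile was 92.6, and among genes of at least 1 RPKM it was 11.9, with 7 members left.

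Meiosis genes were low. Their median of 0.0885 RPKM lay at percentile 0.12, over the 25 genes above 0. With genes at 0 included it lay at percentile 2.57, just inside the range of random lists. SWI1 was the highest at 9.79 RPKM, at a mean weight of 0.322 per clone. AHP2 stood at 0.202 RPKM, and MPS1 was listed at 0, which allows up to 0.333 RPKM. Mitotic cell cycle genes had a median of 0.440 RPKM (percentile 90.8), led by the cytokinesis syntaxin SYP111 at 1.88 RPKM, CDKB2;1 at 0.803 RPKM and AUR1 at 0.624 RPKM, with CYCB2;1 lowest at 0.0324 RPKM.

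The 52 microRNA target genes had a median of 0.340 RPKM (percentile 92.5). NAC1 stood apart at 35.0 RPKM, at a mean weight of 0.257 per clone, ahead of the superoxide dismutase genes CSD1 at 11.6 RPKM and CSD2 at 2.97 RPKM. CUC1 was lowest at 0.0227 RPKM, with an upper counting limit of 0.442. Heat shock genes had a median of 0.272 RPKM (percentile 56.6). The constitutive chaperone gene HSC70-1 stood at 19.8 RPKM, HSFA2 at 0.673 RPKM and HSP18.2 at 0.310 RPKM, and HSP17.6II was listed at 0.

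Markers of other organs were low. Root markers had a median of 0.0916 RPKM (percentile 3.84), and 1 of the 9 above 0 exceeded the median gene, the iron transporter gene IRT1 at 0.282 RPKM (0.0719 to 0.745). EXPA7 and SHV2 followed at 0.169 and 0.130 RPKM, and PHT1;1 was listed at 0. Seed storage genes had a median of 0.0725 RPKM (percentile 2.67), with none of the 7 above 0 over the median gene. SESA4 was highest at 0.182 RPKM, ahead of OLEO2 at 0.134 RPKM and SESA2 at 0.0995 RPKM, and OLEO1 was listed at 0. Percentiles between 2.5 and 97.5 were read as within the range of random lists, so neither other-organ list nor the pollen, mitotic, microRNA target and heat shock lists fell outside it. Other settings gave 2 exceptions. The microRNA targets lay at 98.7 with genes at 0 included. The root markers lay at 0.67 among genes with a mean weight of at least 0.5 per clone, a setting chosen after seeing the data that leaves 4 of them.

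**Figure D1:**
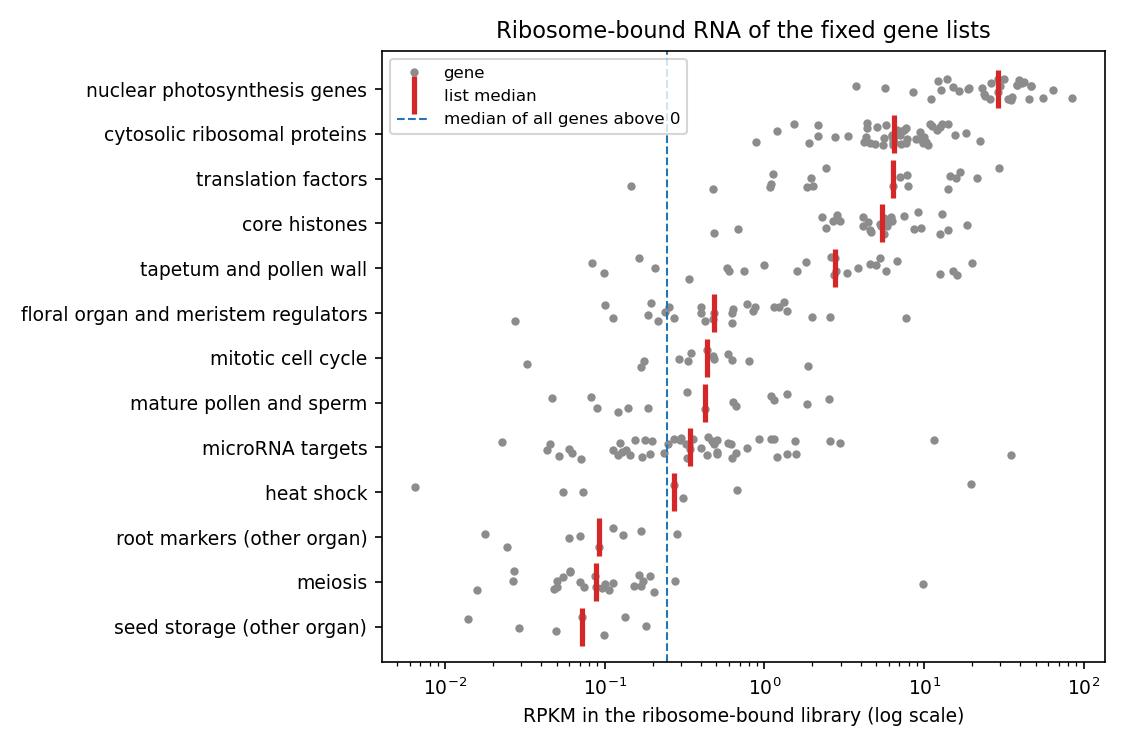
RPKM of each gene of the 13 fixed lists in the ribosome-bound library, on a logarithmic axis, with genes listed at 0 left out. Red bars mark list medians, from 0.0725 RPKM for seed storage to 28.9 RPKM for photosynthesis, and the dashed line marks the median gene at 0.245 RPKM.

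The 20 nuclear protein-coding genes of highest RPKM mixed well-known abundant mRNAs with short or unnamed transcripts. AT2G01021, a transcript of 102 nt at bases 6571 to 6672 of chromosome 2 (TAIR10.1 annotation), reached 6468 RPKM (6309 to 6629). AT3G20362, of 144 nt on chromosome 3, reached 1005 RPKM. The lipid-transfer family gene AT1G18280 followed at 585 RPKM, AT2G07732, annotated with a Rubisco large chain domain, at 361 RPKM, and the G patch gene AT5G59050 at 291 RPKM. AT3G13857 stood at 160 RPKM, the choline kinase gene CK1 at 143 RPKM and the lipid transfer protein gene LP1 at 124 RPKM. Between 50 and 100 RPKM lay PSBR, CAB1, LHCB5 and ATA20, the metallothionein genes MT2B at 77.7 and MT2A at 58.4, and FRS12 at 82.5. The same range held AT1G47970 at 72.3, AT1G57775 at 71.0, AT1G30860 at 63.5, AT1G77030 at 63.3 and AT4G03410 at 58.9. CK1, AT1G77030 and AT3G13857 had mean weights of 0.0791, 0.152 and 0.159 per clone. An exact 20-nt match to a tRNA, rRNA, snRNA or snoRNA, an rDNA locus or an organelle genome was present in 6 of the 20. Such matches covered most of AT2G01021 (rDNA locus) and of AT2G07732 (organelle genomes), so the RPKM of these genes cannot be assigned to nuclear mRNA. AT3G20362, of 144 nt, held 67 different 20-mers of the chloroplast genome and 34 of tRNAs. AT3G13857, CK1 and AT4G03410 held matches too. How much of the RPKM of these further genes came from shared sequence was not tested, so it may not be nuclear mRNA alone.

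Hotspots of the single-stranded library lay mainly on mRNA. Of the bases of the 32785 nuclear hotspots, 69.1% fell in coding sequence (95% interval 68.6 to 69.6, exact binomial on the number of hotspots), 9.38% in 3′ UTRs and 4.47% in 5′ UTRs. Coding sequence makes up 14.0% of both genome strands, a 4.94-fold excess. The comparison with both strands does not allow for which sequence is transcribed, so an excess on mRNA is built into an RNA library. Introns held 8.62% of the hotspot bases, close to their 8.16% of both strands. Non-coding RNA genes held 1.23%, pseudogenes 1.01%, the antisense strand of genes 3.94% and intergenic sequence 2.26%, against 36.3% of both strands for the last.

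Within mRNAs, hotspots favoured the coding sequence over the UTRs. For the 27828 hotspots on 13935 representative mRNAs, each was placed 1000 times at random inside its own spliced transcript. Coding sequence held 1.09 times the hotspot bases of the placements (95% of placements 0.994 to 1.01), 3′ UTRs 0.832 times (0.970 to 1.03) and 5′ UTRs 0.547 times (0.964 to 1.03). All 3 values lay outside every placement. For the 3475 hotspots on transcripts with the same length in both the deposited table and the annotation, the departures were smaller. The 5′ UTR ratio was 0.764 and the coding ratio 1.03, both still outside the placements. The 3′ UTR ratio was 0.918, which lay within the 2.5 to 97.5 percentile range. On single-exon transcripts the departures were larger, with 0.438 for 5′ UTRs, 1.12 for coding sequence and 0.783 for 3′ UTRs.

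Around the start codon, hotspot coverage was low further upstream and rose towards and over the boundary of the coding sequence. On mRNAs with both UTRs of at least 100 nt (21184 hotspots on 10315 mRNAs), the last 100 nt of the 5′ UTR held 0.716 times the bases of the placements (0.949 to 1.05) and the first 100 nt of the coding sequence 1.099 times (0.9503 to 1.05). In bins of 20 nt the ratio rose from 0.484 at 100 to 80 nt upstream to 1.21 over the first 20 nt of the coding sequence. Over the last 20 nt before the start codon it was already 1.07 (percentile 98.9), above the placements. At the other end, the last 100 nt of the coding sequence held 1.25 times the placed bases (0.951 to 1.05) and the first 100 nt of the 3′ UTR 1.01 times, within the placements. The ratio fell from 1.39 at 100 to 80 nt before the end of the coding sequence to 1.11 over its last 20 nt and 0.955 at 20 to 40 nt beyond it, which is within the placements. It then rose to 1.09 at 80 to 100 nt beyond it (percentile 98.9), above the placements. On transcripts of equal length in both sources, with 1546 hotspots on 756 mRNAs, the 2 windows beside the start codon had ratios of 0.889 and 0.961, both within the placements. Among 1000 random sets of 756 of the 10315 mRNAs, the upstream ratio lay at percentile 98.5, above the limits of 0.567 to 0.862, and the downstream ratio at percentile 5.00, within its limits. For single-exon transcripts, with 1965 hotspots, the upstream window stayed low at 0.601 (percentile 0 among the placements), and the first 100 nt of the coding sequence was within the placements at 0.951. In the comparison with 1000 random sets of 1151 mRNAs, which used placements of its own, these 2 windows had ratios of 0.600 and 0.957. They lay at percentiles 2.70 and 2.80, both within the limits of 0.596 to 0.832 and 0.954 to 1.24. The first 100 nt of the coding sequence was also within the placements for hotspots with a score better than the median, at 1.07.

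**Figure D2:**
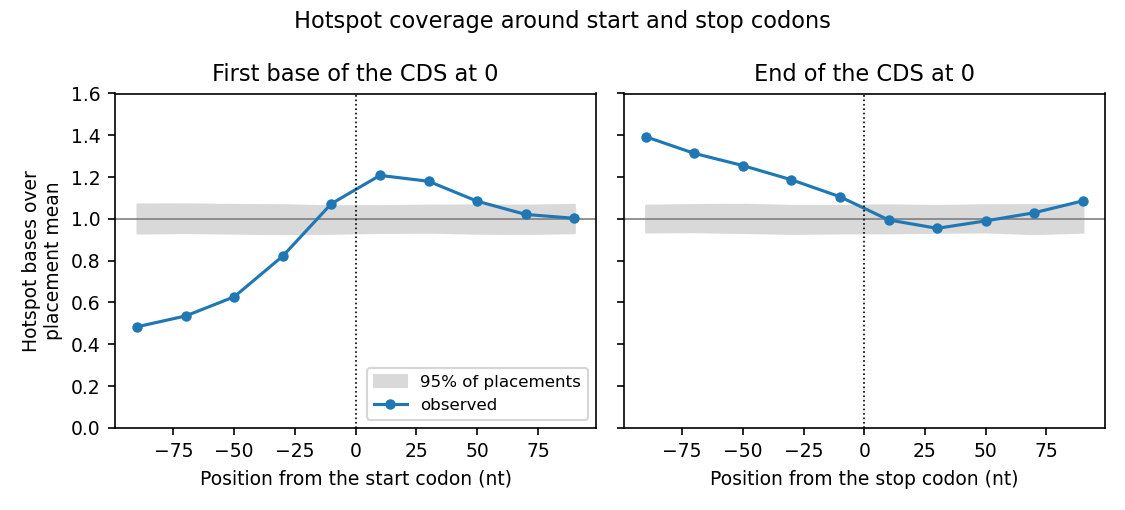
Hotspot bases over the mean of 1000 placements in 20-nt bins on each side of the start codon and of the end of the coding sequence, for 21184 hotspots. The grey band holds 95% of the placements, and the observed ratio climbs from 0.484 to 1.21 across the start codon and drops from 1.39 to 0.995 across the end of the coding sequence.

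The strongest hotspots stood far from the rest on the authors' score. All but 25 had scores between -1.20 and -3.59, and those 25 lay between -10.03 and -16.37. The strongest, at bases 11316208 to 11316258 of chromosome 5 (TAIR9, plus strand), held no exon or intron base of a representative mRNA. The next lay on the chloroplast genome. SIP2 (seed imbibition 2) carried a hotspot of 681 nt on chromosome 3, 470 nt of it coding and 211 nt intronic. LTI78, a cold- and drought-responsive gene, carried the longest hotspot, 1533 nt at bases 21241890 to 21243422 of chromosome 5, of which 1427 nt were coding. The fifth by score, at bases 13715029 to 13715078 of chromosome 3, also held no exon or intron base of a representative mRNA. The annotation used holds no transposable element features, so such elements could not be seen at either place. Among the 25, 19 lay on genes with a representative mRNA, and all 19 genes exceeded the median gene in ribosome-bound RPKM, with a median of 1.61 RPKM.

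Hotspot bases per gene were highest on LTI78, with 1523 nt of its mRNA. GRP7, a circadian RNA-binding protein, ranked 9 of the 10 leading genes, with 1 hotspot over 841 nt, or 722 nt per kb of transcript. Both had a single strong hotspot. The other 8 had very long annotated mRNAs with 9 to 18 hotspots each. These were the auxin transport gene BIG (1209 nt), AT5G23110 (1057 nt), AT4G17140 (1027 nt), AT4G39420 (952 nt), AT5G24350 (912 nt), UPL1 (883 nt), CSI1 (880 nt) and AT5G24740 (840 nt).

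The share of genes with a hotspot rose with ribosome-bound abundance and then fell. In the lowest decile of genes by RPKM 28.1% had a hotspot (95% exact binomial interval 26.3 to 29.99), in the fifth 66.3% and in the eighth 72.8% (70.9 to 74.6). In the highest decile the share was 59.8% (57.8 to 61.8), 13.0 percentage points below the eighth (10.3 to 15.7). Among the 3209 genes listed at 0 RPKM, 12.3% had a hotspot (11.2 to 13.5). The 5 genes of highest RPKM without a hotspot were AT2G01021, AT3G20362, AT1G18280, AT5G59050 and AT3G13857. In the other direction, the genes at or below the median RPKM with the most hotspot bases were AT4G17140 at 0.184 RPKM, AT4G39420 at 0.0202, AT1G76780 at 0.164 (820 hotspot nt), the midasin-like gene AT1G67120 at 0.142 (789 nt) and AT2G25730 at 0.0599 (757 nt). For AT4G39420 the RPKM refers to a listed transcript of 2588 nt, while its hotspots were counted over an annotated one of 10405 nt. Counting only hotspots better than the median score lowered the fall from the eighth to the highest decile to 7.003 points (4.15 to 9.86).

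**Figure D3:**
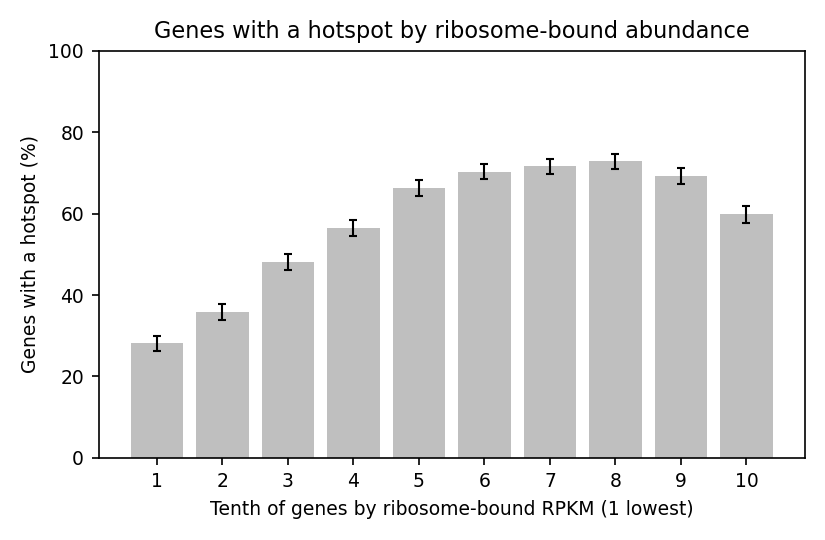
Share of nuclear protein-coding genes with at least 1 hotspot, by decile of ribosome-bound RPKM, about 2342 genes each. Bars start at 0, error bars are 95% exact binomial intervals, and the share climbs from 28.1% to 72.8% in the eighth decile before it drops to 59.8%.

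Across the 13552 genes with a hotspot and an RPKM above 0, hotspot coverage per kb hardly followed ribosome-bound abundance. Spearman's rho across genes was 0.0524 (95% bootstrap interval 0.0357 to 0.0694), and genes are not independent replicates. It was 0.235 (0.223 to 0.247) when all 23423 genes, including those without a hotspot, entered. Among genes of at least 1 RPKM it was 0.0247 (-0.0156 to 0.0675) and among the longest transcripts 0.0242 (-0.00074 to 0.0480), and both intervals included 0. In all, 9 correlations with RPKM were computed. Coverage per kb across genes with a hotspot followed transcript length more closely, with a rho of -0.271 (-0.286 to -0.256). The value of 0.0524 was not adjusted for length.

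Core histone mRNAs carried few hotspots for their abundance. Of the 30 genes, 8 had a hotspot, a share of 26.7% (12.3 to 45.9), where random lists matched on RPKM decile averaged 60.7% (percentile 0.01). With transcript length matched as well, the average was 45.4% and the list lay at percentile 1.79. Length was matched by broad classes only (under 1287 nt, 1287 to 1946 nt and longer), so length within a class was not held equal. The 8 included AT4G40040 and AT5G59690, and HTB4 and HTA8 had none. Cytosolic ribosomal protein genes had a hotspot in 23 of 49 (46.9%, against 60.3%, percentile 3.09), within the range of random lists. None of the 9 root markers and none of the 7 seed storage genes above 0 had a hotspot, against 45.3% and 42.5% in matched lists (percentiles 0.155 and 0.88). These genes rested on at most 3.71 weighted clones (IRT1) and 1.2 (SESA4), so their RPKM deciles are imprecise. Few hotspots therefore cannot be told apart from little or no expression in the buds. A count of 0, taken as 3 counts of the total, allows shares of up to 33.3% and 42.9%, and the exact binomial upper limits were 33.6% and 41.0%. For the seed storage genes the call ended once transcript length was matched (percentile 4.67) or only hotspots better than the median score were counted (percentile 6.08).

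The remaining lists lay within the range of matched lists. Photosynthesis genes had a hotspot in 23 of 34 (percentile 81.6), microRNA targets in 37 of 52 (91.5), mitotic genes in 10 of 13 (80.1) and mature pollen genes in 10 of 15 (66.8). Tapetum and pollen wall genes had one in 15 of 26 (35.6), among them ATA27, GRP17 and EXL4. Translation factors had one in 11 of 19 (36.8), floral regulators in 14 of 27 (6.83), meiosis genes in 12 of 25 (58.5) and heat shock genes in 4 of 7 (58.0). Among the floral regulators PI carried 2 hotspots and SEP3 and AP3 none. The meiosis gene MPS1, listed at 0 RPKM, carried 4.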

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

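The search for shared sequence among the highest genes, the straight line through the score shares, the falls among the shortest and the longest transcripts, the fall among genes with little sequence at other places of the genome and the setting of a mean weight of at least 0.5 were tests chosen after the result was seen. Signals in genes and sequences that the comparisons of the report leave out are given first. The clone shares lie above the 0.000843% of gene clones that a count of 0 allows, a low bar that any class with several clones passes, and this limit says nothing about hotspots. Chloroplast genes held 14.5% of the weighted gene clones of the ribosome-bound library, over 88 genes, and the single gene ATCG00490 held 6.50%. Mitochondrial genes held 1.90% and nuclear pseudogenes 5.01%. In the single-stranded library, 402 hotspots lay on the organelle sequences, 143 on the chloroplast and 259 on the mitochondrial sequence. No explanation was tested for these values.

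The 20 nuclear protein-coding genes of highest RPKM include unnamed and short transcripts. Division by transcript length is argued against as the main reason for the 20 as a set, since 15 were also among the 20 genes with the most weighted clones. The shortest, AT2G01021 and AT3G20362, were among the 15. The rest were PSBR, MT2B, AT3G13857, AT1G57775 and MT2A, with listed lengths of 239 to 720 nt. For these, division by length stays open. Sequence shared with structural RNAs, rDNA or organelle genomes may account for part of the 20. An exact 20-nt match was held by 6 (AT2G01021, AT3G20362, AT2G07732, AT3G13857, CK1 and AT4G03410), a share with an interval of 11.9 to 54.3%. Of the other genes in the highest decile, 3.36% (2.66 to 4.17) held one. In AT2G01021, of 102 nt, 83 different 20-mers matched an rDNA locus. AT2G07732, of 740 nt as annotated, had 681 in the mitochondrial genome and 337 in the chloroplast genome. For AT2G01021 and AT2G07732 the RPKM therefore cannot be assigned to nuclear mRNA. AT3G20362 had 67 in the chloroplast genome and 34 in tRNAs, and AT3G13857 had 82 in snRNA or snoRNA. CK1 and AT4G03410 had 52 and 53 in tRNAs. How much of the RPKM of these further genes came from the shared stretches was not tested, so it may not be nuclear mRNA alone. For the other 14 of the 20, which include PSBR and the metallothionein genes, no match was found, so the explanation stays open for the 20 as a set. No biological explanation was tested.

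The share of genes with a hotspot falls from the eighth to the highest decile of RPKM by 13.0 points. Exon sequence present at other places of the genome is argued against as the main reason, because the fall was 12.9 points (10.1 to 15.7) among genes with a share under 0.1 of their exon 20-mers at other places. The reason for the authors' weights is not given in the sources used here, but the fall was also 13.9 points (11.1 to 16.8) among genes with a mean weight of at least 0.5 per clone. Clones of the ribosome-bound library that map to several places are therefore argued against as the main reason, as far as the mean weight follows such mapping. How reads that map to several places were handled in the single-stranded library is not given, and the weights do not test it. An upper limit on the deposited scores stays open. Among hotspots of up to 6 read equivalents, 38.1% (36.1 to 40.1) in the highest decile had 5 or more, against 34.3% (32.7 to 35.8) in the eighth. That share had already risen from 21.0% in the lowest decile to the eighth, while the share of genes with a hotspot rose too, and a straight line through deciles 1 to 8 gives 38.85% for the highest, so the test does not separate a limit from a general rise with abundance. Shorter transcripts in the highest decile stay open too. The fall was 9.73 points (5.10 to 14.3) at intermediate lengths of 1287 to 1946 nt, 4.97 points (0.0624 to 9.88) among shorter and 7.68 points (3.86 to 11.5) among longer transcripts, and all 3 intervals hold both values above and values below 6.49, which is 0.5 times the whole fall. Whether ribosome-bound mRNAs of the highest decile are more structured was not tested.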

How the results depend on the processing

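Of 185 alternative values, 127 kept their direction and side of the limits or stayed within their interval. Another 9 lost the call but kept their direction, 2 gained a call, 32 moved and 15 changed direction. Some of these 15 also lost their call, namely the window after the start codon on equal-length and on single-exon transcripts. Floral regulators at an RPKM of at least 1 did so too. No value called in one direction was called in the other. Settings with a mean weight of at least 0.5 per clone, at least 3 read equivalents, equal transcript lengths in both sources, single-exon transcripts, the shortest or longest transcripts by decile, or a share under 0.1 of exon 20-mers at other places of the genome were chosen after seeing the data. Where no reason is given, the cause was not tested. Low clone numbers per gene and 1 library per assay limit every value, and list percentiles at an RPKM of at least 1 rest on fewer members.

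For hotspots better than the median score, the shares of bases were 73.9% in coding sequence, 4.22% in 5′ UTRs, 6.59% in introns, 2.28% antisense and 1.55% intergenic, the first 100 nt of the coding sequence had a ratio of 1.07, and the shares of genes with a hotspot in deciles 1, 8 and 10 were 13.9%, 52.6% and 45.6%, which fewer hotspots lower by construction. For hotspots of at least 3 read equivalents they were 72.3% coding, 7.48% intronic, 2.89% antisense and 1.71% intergenic, with decile shares of 18.9%, 62.3% and 51.7%. Counting midpoints gave 8.28% intronic. Ignoring strand gave 71.6% coding, 9.72% in 3′ UTRs, 5.10% in 5′ UTRs, 9.18% intronic, 0.499% antisense and 1.83% intergenic, as bases of the opposite strand were reassigned.

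For transcripts of equal length in both sources, the 5′ UTR and coding ratios were 0.764 and 1.03, still outside the placements but weaker than over all transcripts. The 3′ UTR ratio was 0.918 and the windows before and after the start codon had ratios of 0.889 and 0.961. For single-exon transcripts the latter was 0.951, and the first 100 nt of the 3′ UTR had a ratio of 0.886. With UTRs of at least 50 nt the first 100 nt of the 3′ UTR stood at 0.993. At intermediate transcript lengths the shares in deciles 1 and 10 were 30.2% and 63.4%, and with a mean weight of at least 0.5 the share in decile 1 was 31.6%. With a share under 0.1 of exon 20-mers at other places it was 31.3%. In deciles 1, 8 and 10 the shares were 18.8%, 50.2% and 45.3% for the shortest transcripts and 42.6%, 88.8% and 81.1% for the longest.

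The Spearman correlation between hotspot coverage and RPKM was 0.0247 at an RPKM of at least 1 and 0.0242 among the longest transcripts. At an RPKM of at least 1, floral regulators lay at percentile 11.9 (7 genes), mature pollen at 16.1 (5 genes) and microRNA targets at 17.57 (10 genes), against random lists that were also of at least 1 RPKM. Floral regulators lay at 92.6 with a mean weight of at least 0.5. With genes at 0 included, meiosis lay at 2.57, microRNA targets at 98.7 and heat shock at 40.4. With a mean weight of at least 0.5, root markers lay at 0.67 (4 genes), and the median of translation factors was 2.44 RPKM (13 genes). For hotspots in lists, the percentiles with length matched were 4.67 for seed storage, 19.2 for meiosis, 35.9 for mature pollen and 43.8 for microRNA targets. With hotspots better than the median score they were 6.08 for seed storage, 4.67 for mitotic genes and 42.6 for photosynthesis, and with a mean weight of at least 0.5 they were 52.6 for the tapetum and 36.4 for meiosis. No paired analysis was possible because each assay had 1 library.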

Other observations

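The base composition and GC adjustment were computed on 5000 hotspots inside coding sequences, each with a random segment of equal length from the same coding sequence, and the comparisons of single bases and purines, of hotspots by strength and with shuffled copies were tests chosen after the folding result was seen. Hotspots were richer in purines than their segments, with 56.9% against 52.8%, a difference of 4.07 percentage points (95% bootstrap interval 3.76 to 4.39). More purine than in the paired segment was found in 61.6% of hotspots and less in 33.5%. G was higher by 2.34 points (2.12 to 2.56) and A by 1.73 points (1.47 to 1.97), while C fell by 2.34 points and T by 1.73 points. GC content was 44.3% in both, with a difference whose interval was -0.194 to 0.205 points.

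Predicted folding of hotspots was compared with random segments of the same coding sequence, which could overlap them. The aim was to weigh which kind of nuclease the single-stranded library may have met, because its label names an enzyme that cuts single-stranded RNA. Treatment with such an enzyme would leave paired RNA and so hotspots of lower folding energy. The hotspots instead had a higher mean energy, by 0.00592 kcal per mol per nt (0.00364 to 0.00838), at -0.167 against -0.173, opposite to that prediction. This cannot decide which nuclease was used, because the way the hotspots were called is not given and the difference is small. GC content is argued against as the reason for the difference, because its mean was 44.3% in both hotspots and segments. The difference at equal GC was 0.00594 (0.00393 to 0.00827). It adds no separate support, since with equal mean GC this value had to lie near the whole difference. Base composition, including the purine excess, is argued against as well. Shuffled copies with the same bases differed by -0.000419 (-0.00215 to 0.00135), and after these were subtracted a difference of 0.00634 (0.00462 to 0.00816) was left. With shuffled copies that keep the pairs of neighbouring bases, 0.00482 (0.00313 to 0.00643) was left. The difference is small, with a higher energy in 51.4% of pairs and a lower one in 47.3%, and it was 0.00716 (0.00283 to 0.0120) for hotspots of 1 or 2 read equivalents and 0.00374 for those of 5 or 6, where its interval reached 0 (-4.57e-06 to 0.00767). The energies are predictions for each stretch folded alone, so unpaired RNA as the source remains a hypothesis.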
